A study of Homo sapiens with 18 samples.

How the data were processed

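RNA of 18 cultures was measured: 3 HNSCC lines (Cal27, Detroit562 and FaDu) with a control or a BACH1 hairpin, untreated or given HGF at 30 ng/mL for 3 or 6 h. Cells grew in MEM with 10% fetal bovine serum, RNA was extracted with TRIzol, and stranded poly(A) libraries were made, per the labels' protocols. Groups come from the titles, and the replicate number stands for the cell line, so each of the 6 groups has 3 libraries. Each library is a single culture with 1 population per line and genotype, so p-values cover the spread between these samples, and effects of a line's hairpin, selection or passage cannot be separated from those of BACH1.

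The deposited gene table holds, per the file headers, a read count, TPM and RPKM for each of 60676 Ensembl genes in each library, and a second table the same for 227818 transcripts. Per the file headers the deposited gene values are read counts, taken here as estimated counts that were rounded to whole numbers before deposit. They equalled the sum of the transcripts' counts within 4 counts in every case and exactly in 93.3% of values. Deposited TPM (length-scaled, with the same sum in every library) served as an alternative unit; RPKM was not used here. The build is GRCh38.p13, per the submitters' processing notes; the aligner and the counter are not given in the sources used here, nor is whether counting used strand, so genes that overlap or share near-identical sequence are uncertain. Coordinates are those of the GENCODE annotation given with the data on GRCh38, matched by gene ID. On 34 symbols there was more than 1 gene ID; these were kept apart by ID.

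Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with a minimum count of 10, TMM normalization, and robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error is the log2 fold change divided by the square root of F. For the knockdown over the lines, the 3 time points of a line and genotype were summed and the line was a block (16649 genes). Each line's knockdown, and its difference between lines, came from all 18 libraries with line by time as 9 blocks; HGF comparisons and their interactions with genotype used line by genotype as 6 blocks (16246 genes each). HGF effects within each line, 6 comparisons beside the 11 of the design, were added after the data were seen, as the lines differed. The pairing comes from the line by design. Deviations from the group means correlated at r = 0.819 to 0.927 between libraries of the same line and at -0.336 at most between lines. With 1 library per line in each group, centring makes values between lines negative, so this contrast shows only that the lines differ.

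Before the data were examined, 20 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists cover BACH1 and NRF2 targets, glycolysis, electron transport, matrix proteases, epithelial junctions, mesenchymal genes, immediate-early factors, ERK feedback and output, MET, ERBB and AXL receptors and ligands, NF-kB cytokines, interferon-stimulated genes, proliferation, suprabasal and basal keratinocyte genes, hypoxia response, integrated stress response, cholesterol synthesis, p53 targets, ribosomal proteins, and markers of fibroblasts, endothelium and leukocytes. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison; of 160 planned list tests 67 were called by camera, 8 with an estimated correlation and 29 by fry. Members were also counted adjusted over the list alone.

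BACH1, MET and HMOX1 were named in every comparison. For the knockdown over the lines and HGF at 3 and 6 h, the rule took the 10 largest changes per direction among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and the same sign in every pair; for other comparisons it took 5 per direction, for differences between lines the 10 smallest p, and where none passed the 5 smallest p. From each list it took up to 4 members with the smallest p. CPM are counts scaled to a common library total. A fold against libraries that are all at 0 is given as a bound against 3 counts over the group.

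Alternatives were DESeq2 size factors, no filter beyond a total of 0, DESeq2 1.42.0 tests, limma on log2 TPM with pseudocounts of 1 and 0.1, single time points, each line left out, no line block and each genotype alone. Added after seeing the data were fits without the Cal27 shControl HGF 3 h library, with line-specific HGF effects, with the genotypes summed, and without each culture. The tests were run on simulated counts with known changes before use: a log2 change of 1 was recovered for 99 of 99 genes in the knockdown over the lines (15662 genes run, 11.6% of calls unchanged genes), 97 of 100 for the FaDu knockdown, 93 of 100 for the HGF 3 h interaction and 92 of 100 for HGF 3 h in FaDu. The simulated effects did not vary between lines, and the simulated spread came from a fit with line-specific HGF effects. The real fits over the lines, for the knockdown, HGF and the interactions, carry the differences between lines in their spread. The shares recovered therefore do not hold for those fits. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 and numpy 2.4.6 on Python 3.11.15.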

Results

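The series profiles polyadenylated RNA of 3 head and neck squamous cell carcinoma (HNSCC) lines, Cal27, Detroit562 and FaDu, each carried as a pair of cultures with a control hairpin (shControl) or a hairpin against BACH1 (shBACH1). Every culture was left untreated or given recombinant human hepatocyte growth factor (HGF, the ligand of the receptor tyrosine kinase MET) at 30 ng/mL for 3 or 6 h, which makes 6 groups of 3 libraries with 1 library per line in each group, 18 in all. BACH1 is a heme-regulated transcription factor known to repress antioxidant and heme-degradation genes, among them HMOX1. The title places the work on an interaction of MET with BACH1 in metastasis, so the comparisons ask what the knockdown changed, what HGF changed, and whether the HGF response differed between the genotypes. Total gene counts lay between 15618224 and 25084381 per library. In 17 libraries 65.3 to 68.5% of the 60676 annotated genes had no count, against 51.2% in the Cal27 shControl library at HGF 3 h, where the mitochondrial chromosome also took the highest share of counts, 7.79%.

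BACH1 RNA (ENSG00000156273, chromosome 21, 29194071 to 29630751, plus strand, GRCh38) was lower in the library labelled shBACH1 in 9 of 9 time-matched pairs. In Cal27 it stood at 61.2, 41.9 and 75.8 CPM (counts scaled to the library's total) in shControl at 0, 3 and 6 h and at 29.7, 30.5 and 37.1 in shBACH1. In Detroit562 the shControl values were 35.1, 70.7 and 67.2 CPM and the shBACH1 values 13, 19.5 and 20. In FaDu they were 21.6, 30.7 and 24.2 CPM against 11.2, 10.0 and 10.9. The knockdown therefore left 27.5 to 72.8% of the time-matched control level, the highest share being Cal27 at HGF 3 h. That share rests on the shControl library with the low share of genes without a count. In Cal27 at 0 and 6 h the shares were 48.6 and 48.9%. Over the 3 lines untreated BACH1 averaged 39.3 ± 20.1 CPM in shControl and 18 ± 10.2 in shBACH1 (SD, n = 3). HMOX1, which encodes heme oxygenase-1 (ENSG00000100292, chromosome 22, 35380361 to 35394207, plus strand), was 1.99 to 5.7 times as high in shBACH1 as in shControl in the Cal27 pairs, 60.2 to 76.1 times in Detroit562 and 12.4 to 28.5 times in FaDu. The Cal27 value of 5.7 came from the same HGF 3 h pair.

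**Figure D1:**
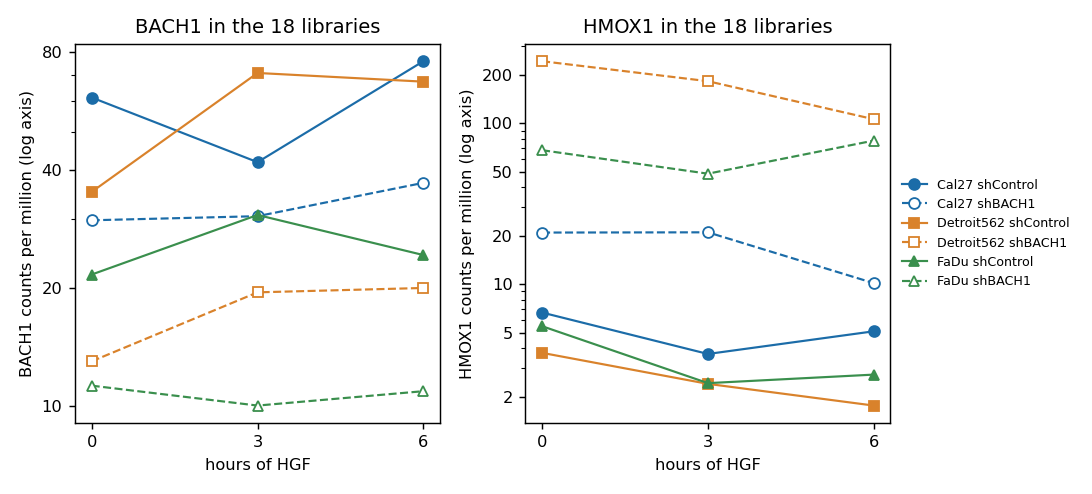
BACH1 (left) and HMOX1 (right) in CPM on log axes against hours of HGF, 1 point per library; solid lines with filled points are shControl cultures and dashed lines with open points shBACH1. BACH1 lay lower in shBACH1 in 9 of 9 time-matched pairs, and HMOX1 in Detroit562 lay at 243, 182 and 106 CPM in shBACH1 against 3.74, 2.40 and 1.76 in shControl.

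The first comparison asks which genes the knockdown changed across the lines, with the time points of each line and genotype summed and the line as the replicate. Antioxidant and carbonyl-reducing enzymes rose: GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, by a log2 fold change of 0.93 ± 0.08 (SE, n = 3 lines, adjusted p = 0.0037), and the aldo-keto reductases AKR1C2 by 0.97 ± 0.12 and AKR1B1 by 0.52 ± 0.07 (both adjusted p = 0.0496). The neuronal cell-adhesion gene NRCAM rose by 2.79 ± 0.15 (adjusted p = 0.00011), the zinc finger gene ZNF469 by 2.46 ± 0.18 (adjusted p = 0.0040) and UNKL, a RING finger gene, by 0.67 ± 0.08. Interferon-stimulated genes fell: the antiviral enzyme RSAD2 (log2 fold change -1.15 ± 0.15), the nucleotide kinase CMPK2 (-0.97 ± 0.12), IFI44L (-0.69 ± 0.09), IFIT3 (-0.67 ± 0.08), the RNA sensor DDX58 (-0.54 ± 0.07) and IFIT2 (-0.54 ± 0.07), with adjusted p between 0.032 and 0.039. All 12 of these genes had the same sign in the 3 lines, which the rule for named genes required. Without Detroit562, NRCAM, AKR1B1, UNKL, IFI44L, IFIT3, DDX58 and IFIT2 did not pass (adjusted p from 0.161 to 0.70). Without the Cal27 shControl HGF 3 h library ZNF469 and AKR1B1 did not (adjusted p = 0.071 and 0.075), and AKR1B1 did not without FaDu either (adjusted p = 0.063).

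BACH1 itself narrowly missed the threshold in this comparison (log2 fold change -1.28 ± 0.14, adjusted p = 0.0501), and HMOX1, whose increase varied between lines, did not pass either (3.95 ± 1.29, adjusted p = 0.997). MET (ENSG00000105976, chromosome 7, 116672196 to 116798386, plus strand) had a log2 fold change of -0.05 ± 0.08 (adjusted p = 0.997). In all, 13 of 16649 genes passed, 6 higher and 7 lower, and 789 had an unadjusted p under 0.05 where 832.4 would by chance. The remaining gene, ASDURF (-3.56 ± 0.48, adjusted p = 0.0398, mean 0.36 CPM), was named after its values were seen. The count was 209 without Cal27 and 47 without FaDu, 64 with DESeq2 and 0 with limma on log2 TPM, so it depends on the lines and tool used.

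Of the 26 BACH1 and NRF2 antioxidant and heme targets tested, 1 rose over all genes (GCLM) and 7 rose adjusted over the list alone; FTH1, a ferritin subunit, had 0.68 ± 0.10 and AKR1C1 0.75 ± 0.13, neither passing over all genes. Camera called the list higher (adjusted p = 7.9e-28), a call lost at adjusted p = 0.13 with an estimated correlation. Of 19 interferon-stimulated genes 5 fell, 18 adjusted over the list alone, and camera called the list lower (adjusted p = 4.2e-76, and adjusted p = 0.13 with an estimated correlation). In the other 18 lists no member passed over all genes. Adjusted over the list alone, 2 of 21 matrix protease genes, 3 of 18 mesenchymal genes and 3 of 16 basal keratinocyte genes fell, and camera called all 3 lists lower (adjusted p = 0.31, 0.41 and 0.39 with an estimated correlation). Camera also called the hypoxia, NF-kB and suprabasal lists lower and the ERK, junction and stress-response lists higher, with an estimated correlation at adjusted p = 0.53, 0.53, 0.62, 0.31, 0.50 and 0.53. It called none of the glycolysis, electron transport, immediate-early, receptor, proliferation, cholesterol, p53 and ribosomal protein lists or the 7 tested markers of fibroblasts, endothelium and leukocytes, in which no member passed over the list alone either.

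Each line's own knockdown was then tested over its 3 time-matched pairs, with the spread shared over all 18 libraries. These tests compare the 2 populations made from 1 line, not independent transductions. BACH1 fell and HMOX1 rose in every line. HMOX1 rose by a log2 fold change of 1.67 ± 0.24 in Cal27, 6.09 ± 0.26 in Detroit562 and 4.17 ± 0.25 in FaDu (adjusted p = 0.034, 2.1e-06 and 1.6e-05), and BACH1 had -0.90 ± 0.12, -1.67 ± 0.12 and -1.25 ± 0.13 (adjusted p = 0.0035, 8.1e-07 and 3.1e-05). MET passed in no line, with -0.15, -0.08 and 0.08 (adjusted p = 0.53, 1 and 0.70). ZNF469, GCLM, FTH1, AKR1C2, AKR1C3 and UNKL rose and RSAD2, IFIT3 and IFI44 fell in all 3 lines, and 12 genes in all were called in every line.

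**Figure D2:**
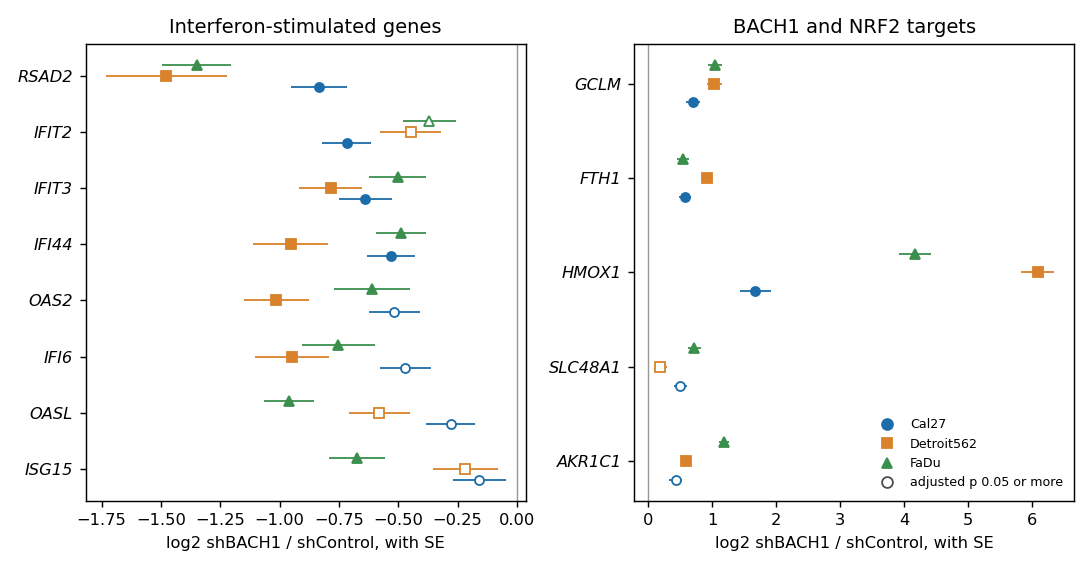
Log2 ratio of shBACH1 to shControl in each line for the interferon-stimulated genes (left) and BACH1 and NRF2 targets (right) named by rule, as the fitted value with its standard error; filled points passed at an adjusted p under 0.05 and open points did not. RSAD2 lay at -0.83 in Cal27, -1.48 in Detroit562 and -1.35 in FaDu, and HMOX1 at 1.67, 6.09 and 4.17.

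In Cal27, 16 genes rose and 22 fell of 16246 tested. Limma on log2(TPM + 1) called 0 (1578 at an unadjusted p under 0.05), and edgeR on the 6 Cal27 libraries alone called 0 (1018). These calls therefore depend on the tool and unit, which changed together, and on the libraries in the fit. AKR1C2 (1.04 ± 0.12) and AKR1C3 (0.81 ± 0.13), which reduce steroids and reactive carbonyls, rose with CEBPA, a transcription factor of differentiation (0.79 ± 0.16, adjusted p = 0.046). IL1B, which encodes interleukin-1 beta, fell (-0.60, adjusted p = 0.0043), as did SNAI2, a repressor of epithelial genes (-0.45, adjusted p = 0.033), and LAMA3, which encodes a basement membrane protein (-0.43, adjusted p = 0.049). Of the 26 BACH1 and NRF2 targets 3 rose, 13 adjusted over the list alone, and the list was called also with an estimated correlation (adjusted p = 0.0046). Of 20 interferon-stimulated genes 4 fell, 17 adjusted over the list alone (camera adjusted p = 1.7e-26, and adjusted p = 0.066 with an estimated correlation). Of 16 hypoxia-response genes none passed over all genes and 7 fell adjusted over the list alone (adjusted p = 0.066 with an estimated correlation). COL8A1 and MYEF2 were called at least 6.15-fold and at least 5.43-fold lower against a floor of 3 counts over the group, since all Cal27 shBACH1 libraries were at 0. Their counts came mostly from the shControl library at HGF 3 h, and without its pair they did not pass (adjusted p = 0.33 and 0.53). Without the untreated, 3 h and 6 h libraries in turn the count of 38 became 12, 363 and 6.

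In Detroit562, 43 genes rose and 44 fell. There were 26 calls with limma on log2(TPM + 1) and 766 with edgeR on the 6 Detroit562 libraries alone. CH25H, which makes 25-hydroxycholesterol, rose by 2.72 ± 0.32 (adjusted p = 0.00026), NRCAM by 2.91 ± 0.13 and ZNF469 by 2.95 ± 0.18. The cell cycle gene CCND2 (-1.38 ± 0.15), the fatty acid hydroxylase CYP4F11 (-1.27 ± 0.16) and IGFBP5, which binds insulin-like growth factors (-1.43 ± 0.26), fell. Of the 26 BACH1 and NRF2 targets 5 rose, 11 adjusted over the list alone (adjusted p = 0.0012 with an estimated correlation), among them FTH1 (0.92), GCLM (1.03) and AKR1C1 (0.60). Of 20 interferon-stimulated genes 6 fell, 17 adjusted over the list alone, with OAS2 at -1.01, IFI6 at -0.95 and IFI44 at -0.95 (camera adjusted p = 2.1e-37, and adjusted p = 0.051 with an estimated correlation). Of the 22 matrix protease genes, 3 fell, MMP2 (-0.51), MMP7 (-0.54) and the inhibitor TIMP3 (-0.45), with PDPN, a mesenchymal-list glycoprotein (-0.66). The hypoxia-response genes EGLN3 (0.58) and NDRG1 (0.57) rose, 2 of 16 on that list (adjusted p = 0.077 with an estimated correlation). Without the untreated, 3 h and 6 h libraries in turn the count of 87 became 37, 239 and 13, and it was 223 without the Cal27 shControl HGF 3 h library.

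In FaDu, 212 genes rose and 286 fell. On log2(TPM + 1) limma called 80 higher and 55 lower, and edgeR on the 6 FaDu libraries alone called 454 genes. HTRA3, a secreted serine protease, rose by 2.83 ± 0.19 and FAM167A by 2.20 ± 0.45. IGFBP5 fell by 2.77 ± 0.52 on the log2 scale and the long noncoding RNA LINC00958 by 2.05 ± 0.48. Of 10 alternatives 4, 3 and 5 did not call FAM167A, IGFBP5 and LINC00958, with smallest changes of 0.247, -0.305 and -0.402. HTRA3 was called in all 10. CA9, a hypoxia-induced carbonic anhydrase, was at 0.0476, 0.128 and 1.11 CPM in shControl and at 0 in the 3 shBACH1 libraries, at least 7.08-fold lower. Its counts came mostly from the shControl library at HGF 6 h, and without that pair it did not pass (adjusted p = 0.574), nor with limma on log2(TPM + 1) (adjusted p = 0.471). Of the 17 integrated stress response genes, 9 rose, 11 adjusted over the list alone, led by the asparagine synthetase ASNS (0.85 ± 0.08), the serine synthesis enzymes PSAT1 (0.80) and PHGDH (0.46), and TRIB3 (0.71) (adjusted p = 0.0038 with an estimated correlation). Of the 17 cholesterol synthesis genes, 9 fell, 13 adjusted over the list alone, among them MVD (-0.85), LSS (-0.66) and FDPS (-0.65) (adjusted p = 0.016 with an estimated correlation). Of the 16 hypoxia-response genes, 8 fell and 1 rose, 11 and 2 adjusted over the list alone, with NDRG1 at -1.17 ± 0.09, EGLN3 at -1.03 and the mitophagy receptors BNIP3 at -0.89 and BNIP3L at -0.71 (adjusted p = 0.0038 with an estimated correlation).

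Keratinocyte genes fell in FaDu too. Of 13 suprabasal genes, 4 fell, 4 adjusted over the list alone: the mucosal keratins KRT4 (-1.2 ± 0.08) and KRT13 (-1.16), FLG (-0.99) and TGM1 (-0.65). Of 16 basal genes 5 fell and 1 rose, 7 and 1 adjusted over the list alone, with KRT15 at -0.80, KRT17 at -0.74 and KRT5 at -0.55. Both lists were called with an estimated correlation (adjusted p = 0.016 and 0.0078). Of 26 BACH1 and NRF2 targets, 10 rose, 10 with 1 lower adjusted over the list alone (adjusted p = 0.0038 with an estimated correlation), with AKR1C1 at 1.19, GCLM at 1.04 and the heme transporter SLC48A1 at 0.72. Of 21 glycolysis genes, 6 fell, 11 adjusted over the list alone, with PDK1 at -0.95 and ALDOC at -0.83, and 9 of 20 interferon-stimulated genes fell, 11 adjusted over the list alone, with OASL at -0.96 (adjusted p = 0.067 and 0.086 with an estimated correlation). Of 22 matrix genes, 5 fell, with MMP12 at -1.27, and SERPINE2 rose (0.75); adjusted over the list alone 6 fell and 1 rose (adjusted p = 0.15 with an estimated correlation). Without the untreated, 3 h and 6 h libraries in turn the count of 498 became 141, 2914 and 69, and it was 1145 without the Cal27 shControl HGF 3 h library.

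Whether the knockdown effect differed between lines was tested by the interaction of genotype and line. The effect differed for 151 genes. KRT4, the hypoxia-response genes EGLN3 and NDRG1, and CP, which encodes the ferroxidase ceruloplasmin, rose in Detroit562 (0.46, 0.58, 0.57 and 0.52) and fell in FaDu (-1.2, -1.03, -1.17 and -1.2), with interaction adjusted p of 1.36e-06, 5.71e-06, 5.71e-06 and 6.77e-05. ASNS, CREB3L2 and TBL1X had 0.85, 0.97 and 1.08 in FaDu and lay between -0.23 and 0.09 in the other lines, and ALDOC and LSS had -0.83 and -0.66 in FaDu against -0.09 to 0.35. HTRA3 rose most in FaDu. The increase of HMOX1 differed between lines (adjusted p = 0.00162); the decrease of BACH1 (adjusted p = 0.071) and the MET values (adjusted p = 0.59) did not pass. The count was 33, 2578 and 8 without the untreated, 3 h and 6 h libraries, and 498 without the Cal27 shControl HGF 3 h library.

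The HGF comparisons ask how cultures given HGF differed from untreated ones, first as the mean over both genotypes and the 3 lines. The design holds no vehicle-treated culture at 3 or 6 h. In every line an effect of HGF therefore cannot be told from a change with time in culture. At 3 h the feedback inhibitor of receptor signalling SPRY4 rose by 4.24 ± 0.81 (log2, SE, n = 6 cultures, adjusted p = 0.014), with PHLDA1 (3.30 ± 0.70), the cytokines LIF (3.41 ± 0.75) and IL11 (3.35 ± 0.59), the EGF receptor ligands AREG (3.04 ± 0.65) and EREG (2.99 ± 0.55), and SERPINB2, an inhibitor of plasminogen activators (3.06 ± 0.43, adjusted p = 0.0046). The signalling scaffold AKAP12 (3.03 ± 0.67), the hyaluronan synthase HAS3 (2.84 ± 0.64) and the pseudogene transcript RPSAP52 (3.85 ± 0.69) rose as well. Among genes that fell were the pro-apoptotic BMF (-2.82 ± 0.69), the exchange factor VAV3 (-2.27 ± 0.63), the epithelial transcription factor ELF3 (-1.84 ± 0.43), the proline dehydrogenase PRODH (-1.77 ± 0.37), the antigen presentation regulator CIITA (-1.73 ± 0.26) and TP73, a p53 family member (-1.69 ± 0.19, adjusted p = 0.0022). RBBP8NL, STON1, SH2D3C and TENT5B also fell, by log2 values from -1.99 to -1.66. BACH1 (0.38 ± 0.19, adjusted p = 0.19), MET (0.27 ± 0.18, adjusted p = 0.34) and HMOX1 (-0.44 ± 0.20, adjusted p = 0.17) did not pass.

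In all 1205 genes rose and 844 fell at 3 h of 16246 tested; limma on log2(TPM + 1) gave 600 and 915. Of 20 ERK feedback and output genes, 10 rose, 13 adjusted over the list alone, with CCND1 (1.18), ETV4 (0.84) and DUSP7 (1.68). Of 22 matrix protease genes, 8 rose, 9 adjusted over the list alone, with MMP3 at 2.13 and ADAMTS1 at 1.28, and 5 of 16 basal keratinocyte genes rose, 8 adjusted over the list alone, with KRT17 at 1.59. Camera called these 3 lists, each at adjusted p = 0.38 with an estimated correlation. Of 17 receptor and ligand genes, 5 rose and ERBB3 fell (-0.88), 8 and 1 adjusted over the list alone, and 5 of 21 glycolysis genes rose, 7 adjusted over the list alone (both adjusted p = 0.47 with an estimated correlation). Of 22 proliferation genes, 7 fell, among them AURKA (-0.53), CENPF (-0.52) and PLK1 (-0.40), and RRM2 rose (0.46); adjusted over the list alone 9 fell and 2 rose (adjusted p = 0.63 with an estimated correlation). Only 3 of 23 immediate-early genes passed, SRF (0.79), NR4A3 (1.80) and KLF6 (1.65), 3 adjusted over the list alone (adjusted p = 0.56 with an estimated correlation).

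At 6 h 652 genes rose and 458 fell; limma on log2(TPM + 1) gave 200 and 296. IL1RL1, the receptor for interleukin-33, rose by 6.93 ± 1.05 (adjusted p = 0.011), with IL11 (3.04 ± 0.60), the endothelin receptor EDNRA (2.38 ± 0.41), NAV3 (2.34 ± 0.57) and TFPI2, a serine protease inhibitor of the matrix (2.32 ± 0.37). RPSAP52 (5.56 ± 0.63), AKAP12 (2.72 ± 0.68), MIR100HG (2.52 ± 0.45) and SERPINB2 (2.42 ± 0.45) rose too. PLEKHS1 (-2.15 ± 0.24, adjusted p = 0.0015), the BMP and WNT antagonist SOSTDC1 (-1.99 ± 0.41), COLCA2 (-1.84 ± 0.27), the xenobiotic-metabolizing CYP1A1 (-1.70 ± 0.19) and PRODH (-1.56 ± 0.37) fell. BACH1 (0.49 ± 0.19, adjusted p = 0.12), MET (0.43 ± 0.18, adjusted p = 0.14) and HMOX1 (-0.58 ± 0.20, adjusted p = 0.096) did not pass.

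Of 21 glycolysis genes, 10 rose at 6 h, 16 adjusted over the list alone, with PFKP (0.70), LDHA (0.48), PGK1 (0.43) and the lactate exporter SLC16A3 (0.64). Of 16 hypoxia-response genes, 6 rose, 8 with 1 lower adjusted over the list alone, with NDRG1 at 1.22 ± 0.12, BNIP3 at 0.94 and EGLN3 at 0.62. Of 22 matrix protease genes, 7 rose, 15 adjusted over the list alone, with MMP3 (2.25), SERPINE2 (0.74) and TIMP1 (0.40), and 7 of 16 basal genes rose, 9 with 1 lower adjusted over the list alone, with the adhesion receptors CD44 (1.09 ± 0.12) and ITGA3 (0.77). Camera called these 4 lists, each at adjusted p = 0.15 with an estimated correlation. Of 20 interferon-stimulated genes, 5 rose, 13 adjusted over the list alone, with RSAD2 at 1.12, MX1 at 1.08 and IFI6 at 0.95 (adjusted p = 0.30 with an estimated correlation). Among 20 ERK genes and 18 mesenchymal genes, 3 of each rose. Adjusted over the list alone 8 of each rose and 1 mesenchymal gene fell (adjusted p = 0.30 with an estimated correlation for both lists). The counts at 3 and 6 h treat the 2 cultures of each line as independent: with the genotypes summed and 3 lines as replicates edgeR called 0 genes at either time (3285 and 2763 at an unadjusted p under 0.05) and DESeq2 1029 and 513. Without Cal27, Detroit562 and FaDu in turn the counts became 914, 664 and 48 at 3 h and 401, 30 and 243 at 6 h.

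Between 3 and 6 h 182 genes rose and 80 fell; limma on log2(TPM + 1) gave 23 and 5. NDRG1, a stress- and hypoxia-induced gene, rose by 1.35 ± 0.12 (n = 6 cultures, adjusted p = 0.00027), with the potassium channel gene KCNQ5 (1.91 ± 0.14, adjusted p = 4.4e-05), KIF26B (2.31 ± 0.31), BNIP3 (1.06), ENO2 (0.92) and the glucose transporter SLC2A1 (0.66). The immediate-early receptor NR4A3 (-1.96 ± 0.35), STX11 (-1.64 ± 0.19), ADAMTS16 (-1.25 ± 0.27), the transcription factors TWIST1 (-0.80) and SRF (-0.71) and the cholesterol synthesis gene HMGCS1 (-0.48) fell. BACH1, MET and HMOX1 had 0.11, 0.16 and -0.14 (adjusted p = 0.83, 0.70 and 0.80). The count of 262 was 1 with 3 lines as replicates, and 4, 577 and 1 without Cal27, Detroit562 and FaDu.

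Since the lines responded differently, HGF was also tested within each line over its 2 cultures, a comparison added after the data were seen. With all 18 libraries in the fit Detroit562 had the most calls, with 2762 genes higher and 1967 lower at 3 h and 3658 and 3056 at 6 h. On log2(TPM + 1) limma gave 1521 and 2156, and 2095 and 3647, around a median over all genes of -0.118 at both times. At 3 h this ranking did not hold in every fit that left out 1 culture. IL1RL1 rose from 0.267 and 0.489 CPM untreated to 276 and 348 CPM at 6 h (log2 9.95 ± 0.26, n = 2 cultures, adjusted p = 1.9e-13), and RELN, an extracellular matrix glycoprotein, by 7.05. MET and BACH1 both rose in this line: MET by 0.69 ± 0.11 at 3 h and 1.09 ± 0.11 at 6 h (adjusted p = 0.0001 and 5.4e-07), BACH1 by 1.07 ± 0.15 and 1.06 ± 0.15 (adjusted p = 2.6e-05 and 2.7e-05). HMOX1 had -0.21 at 3 h (adjusted p = 0.62) and fell at 6 h (-0.91 ± 0.29, adjusted p = 0.028). At 3 h 21 of 23 immediate-early genes rose, 21 adjusted over the list alone, with FOSL1 at 5.77, EGR3 at 6.13 and MYC at 2.81 (adjusted p = 0.00010 with an estimated correlation). Of 20 ERK genes, 17 rose and 1 fell, 17 and 1 adjusted over the list alone, with DUSP5 at 5.23 and SPRY4 at 5.76 (adjusted p = 0.0025 with an estimated correlation). Of 19 NF-kB cytokine genes, 14 rose, 14 adjusted over the list alone, with the prostaglandin synthase PTGS2 at 4.70, and 16 of 22 matrix genes, 17 adjusted over the list alone (adjusted p = 0.00065 and 0.0083 with an estimated correlation). At 6 h MMP1 (2.86) and HMGA2 (2.78) had risen, and 17 of 22 proliferation genes had fallen, 17 adjusted over the list alone, with TOP2A at -0.82 (adjusted p = 0.086 with an estimated correlation). Without the shControl or the shBACH1 culture the counts became 2151 or 2018 at 3 h and 3609 or 3091 at 6 h.

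In Cal27 753 genes rose and 416 fell at 3 h and 507 and 241 at 6 h. The counts from limma were lower, 85 and 48 at 3 h and 110 and 40 at 6 h on log2(TPM + 1), and 63 and 28, and 81 and 21 on log2(TPM + 0.1). SPRY4 rose by 3.33 and 3.67, FOSL1 by 2.58 and 1.94 and MYC by 1.38 and 1.27 at 3 and 6 h, and DUSP6, a phosphatase of ERK, by 3.45 ± 0.21 at 6 h. BMF (-1.96 ± 0.19), ELF3 (-1.84 ± 0.14) and VAV3 (-1.65) fell at 3 h. ERK genes rose in 14 of 20 cases at 3 h and 13 at 6 h, 16 and 15 adjusted over the list alone (adjusted p = 0.019 and 0.0040 with an estimated correlation). At 6 h 10 of 16 hypoxia-response genes rose, 13 adjusted over the list alone, with BNIP3 at 1.44 and NDRG1 at 1.42, as did 15 of 20 interferon-stimulated genes, 17 adjusted over the list alone, with IFI6 at 1.27 and MX1 at 1.2, and 9 of 21 glycolysis genes, 14 adjusted over the list alone, with ENO2 at 1.35 (adjusted p = 0.0012, 0.037 and 0.037 with an estimated correlation). MET (-0.28 and 0.08, adjusted p = 0.14 and 0.82), BACH1 (-0.18 and 0.33, adjusted p = 0.48 and 0.23) and HMOX1 (-0.20 and -0.77, adjusted p = 0.73 and 0.21) did not pass. SOX5, GREB1L, CNTNAP2, PEG10 and NKX6-1 were called higher at 3 h from 6 to 10 counts in all, at least 4.23, 3.81, 3.38, 2.96 and 2.54-fold against a floor of 3 counts over the group. Without the shControl HGF 3 h library NKX6-1 alone of these passed (adjusted p = 0.037), and the 3 h and 6 h counts became 710 and 1414; without the whole shControl or shBACH1 culture they were 484 or 3029 at 3 h and 529 or 216 at 6 h.

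In FaDu 1406 genes rose and 1049 fell at 3 h and 468 and 374 at 6 h. With limma on log2(TPM + 1) there were 485 and 487 at 3 h and 74 and 116 at 6 h, so the excess of higher genes depends on the tool and unit. Here immediate-early genes fell: EGR1, a serum- and ERK-induced transcription factor, by log2 values of -4.37 ± 0.13 and -4.77 ± 0.13 at 3 and 6 h (n = 2 cultures, adjusted p = 7.9e-13 and 2.9e-13), FOS by -4.81 ± 0.18 and -4.38 ± 0.17, and JUN by -1.2 and -2.31 ± 0.11. EGR1 stood at 599 and 590 CPM in the untreated FaDu cultures, against 7.87 to 58.0 CPM in the untreated cultures of the other lines. Of 23 immediate-early genes, 10 fell and 6 rose at 3 h, 10 and 10 adjusted over the list alone, and 14 fell and 1 rose at 6 h, 14 and 2 adjusted over the list alone (adjusted p = 0.0099 and 2.7e-05 with an estimated correlation). ERK genes rose at 3 h in 13 of 20 cases with 1 lower, 14 and 1 adjusted over the list alone, led by SPRY4 (3.40), PHLDA1 (3.38) and ETV5 (2.39) (adjusted p = 0.021 with an estimated correlation); at 6 h 2 rose and 3 fell, 2 and 5 adjusted over the list alone, with DUSP1 at -2.23 (adjusted p = 0.35 with an estimated correlation). CCN2, a matricellular growth factor gene, fell by 2.86 ± 0.16 on the log2 scale at 6 h. IL1RL1 (4.82 ± 0.22 at 3 h, 4.24 ± 0.22 at 6 h), EDNRA (3.90 and 3.88) and MMP3 (3.53 at 6 h) rose. Of 8 alternatives 3 at 3 h and 5 at 6 h did not call EDNRA, with smallest changes of 0.403 and 0.313. IL1RL1 was called in all 8 at both times. MET rose at 3 h (0.43 ± 0.11, adjusted p = 0.015) and had 0.15 at 6 h (adjusted p = 0.50); BACH1 had 0.32 and 0.15 (adjusted p = 0.20 and 0.68) and HMOX1 -0.58 and -0.05 (adjusted p = 0.23 and 0.97). The count at 6 h was 1695 without the Cal27 shControl HGF 3 h library, and without the FaDu shControl or shBACH1 culture the counts were 503 or 1351 at 3 h and 95 or 190 at 6 h.

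**Figure D3:**
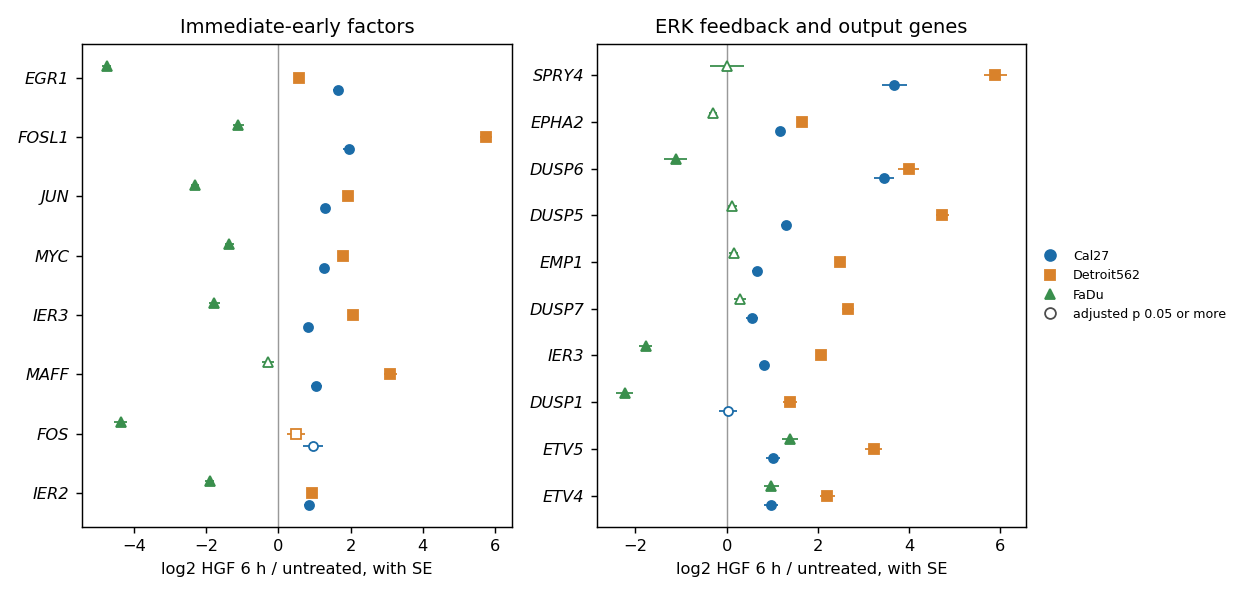
Log2 ratio of HGF 6 h to untreated in each line for the immediate-early factors (left) and ERK feedback and output genes (right) named by rule, as the fitted value with its standard error over 2 cultures; filled points passed at an adjusted p under 0.05 and open points did not. EGR1 lay at 1.66 in Cal27, 0.58 in Detroit562 and -4.77 in FaDu, and ETV5 at 1.39 in FaDu.

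The HGF effect differed between lines for 3919 genes, led by EGR1 (adjusted p = 8.04e-14), CCN2 and JUN (both 3.45e-11), and by FAM83A, DUSP5, FOS and PTGS2 (all 7.11e-11). The difference passed for MET (adjusted p = 0.00011) and BACH1 (0.00169) and did not for HMOX1 (0.18). DUSP5 had 1.10, 5.23 and 0.92 at 3 h in Cal27, Detroit562 and FaDu, and PTHLH, which encodes a parathyroid hormone-like hormone, 0.93, 4.27 and 1.3. FAM83A, a scaffold of EGF receptor signalling, had 0.00, 3.06 and 0.03 at 6 h. Without the Cal27 shBACH1 culture the count was 6040, and without the Detroit562 shControl or shBACH1 culture 1594 or 1377.

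The last comparison asks whether the response to HGF depended on BACH1, by the interaction of time and genotype over the 3 lines. No gene passed at either time with edgeR on the genes kept by the low-count filter. At an unadjusted p under 0.05 there were 103 genes at 3 h and 70 at 6 h where 812.3 would by chance. DESeq2 called 7 genes at 3 h (AL022238.4, AC005832.4 and the 5 with the smallest edgeR p) and 2 at 6 h (ZNF625-ZNF20 and AC005832.4). Limma on log2(TPM + 1) called the same 5 at 3 h and 0 at 6 h. With only genes at a total of 0 removed, edgeR called these 5 at 3 h too (adjusted p = 0.028). BACH1 had an interaction log2 value of -0.21 ± 0.37 at 3 h and -0.14 ± 0.37 at 6 h, MET 0.04 ± 0.35 and 0.07 ± 0.35, and HMOX1 0.58 ± 0.41 and 0.19 ± 0.41 (n = 3 lines, adjusted p = 1 for each). The smallest edgeR p at 3 h belonged to the small nuclear RNA genes RNU1-1, RNU1-3, RNU1-28P and RNVU1-18 and to AC213203.2 (adjusted p = 0.47), near-identical copies that share reads. At 6 h it belonged to PDGFRL, ZNF709, AC005538.2, FAM95C and SULT1A4 (adjusted p = 1). No list was called at 3 h; at 6 h camera called the interferon-stimulated, proliferation and cholesterol lists (adjusted p = 0.039 each, and adjusted p = 0.997 with an estimated correlation), with no member passing over all genes or adjusted over the list alone. The model averages the HGF effect over lines that differ in it, so these differences enter its spread and the standard errors above. For EGR1 the standard error at 3 h was 3. The low number of small p therefore does not show that the genotypes responded alike. With line-specific HGF effects, added after the data were seen, 1 gene passed at 3 h, AC005832.4 (log2 -17.64, adjusted p = 0.00035). At 6 h 3 passed, AC005832.4, SULT1A3 and AC099329.1 (log2 -17.06, 2.88 and 8.26, adjusted p = 0.0011, 0.0042 and 0.0065). In DESeq2 AC005832.4 had -44.92 at 3 h and -43.52 at 6 h, AL022238.4 -23.56 and ZNF625-ZNF20 45.67. Mean levels of AC005832.4, AL022238.4 and ZNF625-ZNF20 were 1.58, 0.323 and 0.228 CPM. The log2 values of these genes are larger than counts at such means can give. Their calls therefore do not show that the response depended on BACH1. This does not cover AC099329.1 and SULT1A3, at means of 1.44 and 9.03 CPM, and for them the question stays open. Neither passed in the fit that averages the HGF effect over lines. The 5 genes with the smallest edgeR p at 3 h had a mean of 0.591 CPM each. The genes called by these alternatives were named after their values were seen.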

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

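The test of the untreated levels in FaDu was planned before its result was seen; the test of library scaling used below was chosen only after the results were seen. The comparisons within each line on which they rest, and the comparison with other genes that fell, were added after the data were seen. Groups hold 3 samples each, too few to test a single library against its group.

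The knockdown effect differed between lines for 151 genes. The smallest adjusted p values of this difference belonged to KRT4 (1.36e-06), EGLN3 and NDRG1 (5.71e-06 each), CP (6.77e-05), ASNS (0.000197), CREB3L2 and HTRA3 (0.000359 each), ALDOC (0.000481), LSS (0.000543) and TBL1X (0.00162), and HMOX1 also differed (0.00162). Of 100 assignments of the 9 time-matched pairs to 3 lines, the real one called 151 genes and the highest other 87, so chance is excluded with the pairs as units, with 1 of 100 splits giving as many. The 3 pairs of a line come from 1 pair of populations, so this does not extend to other populations of these lines. Limma on log2(TPM + 1) and log2(TPM + 0.1) called 11 and 8 genes for the same difference.

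The response to HGF changed between 3 and 6 h for 262 genes. The response differed between lines for 3919 genes, with adjusted p values of 8.04e-14 for EGR1, 3.45e-11 for CCN2 and JUN, 7.11e-11 for FAM83A, DUSP5, FOS and PTGS2, 1.27e-10 for FOSL1, 2.42e-10 for IER3 and PTHLH, 0.00011 for MET and 0.00169 for BACH1.

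Immediate-early genes fell after HGF in FaDu, 14 of 23 at 6 h, while 9 rose in Cal27 and 17 in Detroit562. Library scaling is argued against: a factor of a library moves all genes alike, and the 23 members lay lower than the other genes (median log2 change -1.11 against 0.00176, adjusted p = 2.74e-05 with an estimated correlation). The test planned first, a refit with DESeq2 size factors, moved the median over all genes by 0.012 and so decides nothing. A candidate explanation is a high level in the untreated FaDu cultures: over the 14 genes the median log2 ratio of untreated FaDu to the untreated cultures of the other lines was 2.15 (range -1.58 to 6.09, above 0 for 12). FaDu at 6 h lay at a median of 0.321 against the same untreated cultures, and at -0.68 against the 6 h cultures of the other lines. Genes picked for a fall favour a high untreated value, but the 360 genes outside the list that fell in FaDu at 6 h had a median untreated ratio of 0.0741, and the 65 of them that fell at least as far as the smallest fall of the 14 had -0.24. The 9 list members that did not fall had -0.37, and all 23 members 0.939. The fall may therefore reflect the state of the untreated FaDu cultures rather than repression by HGF. Both untreated FaDu cultures share this level, and the design holds no vehicle-treated culture at 3 or 6 h, so a change with time in culture and an effect of HGF in this line stay open and were not tested.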

How the results depend on the processing

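The fits without the Cal27 shControl HGF 3 h library, with line-specific HGF effects, with summed genotypes, within each line, without each culture, and the difference of knockdown effects with 1 time left out were chosen only after the data were seen. Of 7069 values of the named genes under the alternatives (724 pairs of gene and comparison), 5139 kept their side of the threshold (some genes not called changed sign), 1879 lost the call, 51 gained it and 0 changed direction as a call. The last number says little, since the named genes were mostly chosen for being called and every alternative reuses the same libraries. Counts of calls moved more, and the cause was not tested except where fewer samples enter. The knockdown over the lines (13) gave 219 with only genes at a total of 0 removed, 64 with DESeq2, 0 with limma on log2(TPM + 1) and 0 with log2(TPM + 0.1), 2 and 3 with HGF 3 h or 6 h libraries only, 41 with 18 libraries as independent, and 9 to 209 with a line left out. With the low-count filter removed, Cal27 gave 399, Detroit562 242, FaDu 765, the difference between lines 710, HGF 3 h in Cal27 1799 and the 3 h interaction 5. DESeq2 gave 77 in the Cal27 knockdown, 293 for the difference between lines, 2156 for HGF 6 h, 857 for 6 h against 3 h, and 7 and 2 for the interactions. Limma on log2(TPM + 1) and log2(TPM + 0.1) gave 0 and 0 for the knockdown in Cal27, 26 and 18 in Detroit562, 135 and 135 in FaDu, 11 and 8 for their difference, 496 and 520 for HGF 6 h, 28 and 35 for 6 h against 3 h, 5 and 5 for the 3 h interaction, 1732 and 1288 for the HGF difference between lines, 133 and 91 for HGF 3 h and 150 and 102 for 6 h in Cal27, 972 and 916 and then 190 and 216 in FaDu, and log2(TPM + 0.1) gave 3113 for Detroit562 at 3 h. Without the untreated, 3 h or 6 h libraries the knockdown gave 12, 363 and 6 in Cal27, 37, 239 and 13 in Detroit562, 141, 2914 and 69 in FaDu, and 33, 2578 and 8 for their difference; on its own 6 libraries Cal27 gave 0 (1018 at an unadjusted p under 0.05) and Detroit562 766. Leaving out the Cal27 shControl HGF 3 h library gave 223 in Detroit562, 1145 in FaDu and 498 for their difference, and 710, 1414 and 1695 for HGF in Cal27 at 3 h and 6 h and FaDu at 6 h. Leaving out a line gave 48 to 914 for HGF 3 h, 30 to 401 for 6 h and 1 to 577 for 6 h against 3 h; shControl cultures alone gave 0, 3 and 3 and shBACH1 cultures alone 0, 7 and 8. Summing the genotypes gave 0, 0 and 1 with edgeR and 1029 and 513 with DESeq2 for HGF 3 h and 6 h. Line-specific HGF effects gave 1 and 3 in the interactions. Leaving out 1 culture gave 1377 to 6040 for the HGF difference (1594 without Detroit562 shControl), 484 to 3029 and 216 to 529 in Cal27 at 3 h and 6 h, 2018 to 2151 and 3091 to 3609 in Detroit562, and 503 to 1351 and 95 to 190 in FaDu. Without the line as a block, the pairing being by line, 0 genes were called in the knockdown, in HGF 3 h, 6 h and 6 h against 3 h, and 0 in both interactions, as with it; other results were not refitted without the block. Camera called 67 lists, camera with an estimated correlation 8, and fry, which tests another null hypothesis, 29. Folds of genes at 0 in all libraries of 1 side rest on the floor. Whether depth limited the calls for other genes of few counts was not tested.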

Other observations

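The tests of single libraries for the interferon-stimulated genes and of library depth for the Cal27 shControl HGF 3 h library, and the 32 splits that part every pair, were chosen only after the results were seen; the other tests were written down before.

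Outside the fixed lists, some genes were called in the same direction in the knockdown of a pair of lines; those of this paragraph were picked after their values were seen, and no theme was tested over them. NQO2, a quinone reductase, rose in Detroit562 (0.70) and FaDu (0.47), as did ABCA12, a lipid transporter of keratinocytes (0.67 and 0.89), PTGES, a prostaglandin E synthase (0.42 and 0.36), and FBXO30 (0.59 and 0.55). The antiviral genes DDX60 (-0.54 and -0.91 in Detroit562 and FaDu), MX2 (-0.59 and -1.09 in Cal27 and Detroit562) and XAF1 (-0.69 and -1.07 in the same lines) fell, with the thrombin receptor F2R (-0.58 and -0.46) and the integrin subunit ITGB2 (-0.60 and -0.50) in Detroit562 and FaDu. In all 12 genes were called in 3 lines and 31 in exactly 2. For Detroit562 and FaDu 17 genes were called higher in both and 14 lower in both, where independent lists would share 0.561 and 0.775. Another 5 went opposite ways. For Cal27 and Detroit562 the numbers were 8 higher, 7 lower and 0 opposite, with 0.0423 and 0.0596 for independent lists. For Cal27 and FaDu they were 7, 7 and 2, with 0.209 and 0.387. The lists are not independent, since 1 fit of all libraries gives each gene a shared spread. The number expected to go opposite ways was not computed. Across 9675 genes, which are not independent replicates, the knockdown effects correlated at r = 0.234 (rho = 0.227) between Cal27 and Detroit562, 0.0547 (rho = -0.128) between Cal27 and FaDu and 0.261 (rho = 0.0846) between Detroit562 and FaDu.

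Interferon-stimulated genes were lower in shBACH1, with a list median log2 change of -0.542 over the 3 lines; camera's call of the list over the lines was lost with an estimated correlation (adjusted p = 0.13). Variation of single libraries is argued against: the list median was below 0 in 9 of 9 time-matched pairs, from -0.314 to -1.11. A trend with expression level is argued against too: the median lay at percentile 0 of 10000 random lists matched on mean expression, whose lowest was -0.0797, although such lists do not carry the correlation between members. A hypothesis is that reduced BACH1 lowers interferon-stimulated transcripts in these lines. A difference between the derived populations other than BACH1 (hairpin sequence, selection, passage) could also give it and cannot be told apart, since there is 1 shBACH1 population per line.

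The Cal27 shControl HGF 3 h library held counts in 29620 genes, against 19095 to 21080 in the other 17. Library depth is argued against: after thinning each library to the smallest total, 56.1% of genes were at 0 here and 67.9 to 70.0% in the others. RNA from another of the lines is argued against as well, since 76.4% of the 8123 genes found in no other Cal27 library were at 0 in all Detroit562 and FaDu libraries, against 41.6 to 46.4% for such genes of the other Cal27 libraries. Reads spread over annotated sequence regardless of expression, as from genomic DNA or unspliced RNA, are a candidate explanation: among 31563 genes at 0 in the other 17 libraries the count here rose with exon length (Spearman rho = 0.491 across the 30247 with a length, 95.8%), and 0.172, 6.61, 18.9 and 49.5% were detected in order of length from the shortest to the longest genes, in 4 bins of nearly equal size. Longer transcripts yield more reads from any source of RNA at a low level. Intronic and intergenic reads were not examined, so the trend does not set this candidate apart. The 8123 genes found in no other Cal27 library took 0.112% of this library's counts, and no biological explanation was tested.

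The weight of HGF responses in shBACH1 on those in shControl was tried as a measure of whether knockdown weakens the HGF response. The slope across 9675 genes was 0.638 and 1.16 in Cal27 at 3 and 6 h, 1.02 and 1.06 in Detroit562, and 0.795 and 0.992 in FaDu. The lowest, 0.638, involves the Cal27 shControl HGF 3 h library, and with slopes on both sides of the bound of 0.8 set beforehand the test did not decide.

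Other splits of the libraries were fitted as a check on the counts of calls. For the knockdown over the lines, 3 of 10 splits called as many as the real 13. The highest other called 107, in a split that parts the FaDu pair alone. With the line as a block, that split compares the FaDu genotypes, so it does not stand for chance. Among splits that part all pairs the highest other was 3. In Cal27 3 of 10 splits called as many as the real 38. The highest other called 1850, in a split that parts the HGF 3 h pair alone. With line by time as blocks, that split compares the shControl HGF 3 h library with its shBACH1 partner, so it does not stand for chance. The highest other that parts all pairs called 1. In Detroit562 and FaDu 1 of 10 splits called as many as the real one, with real counts of 87 and 498 and highest others of 4 and 2. With 10 splits the number is too small for a share under 0.05. For HGF 3 h, 1 of 100 splits gave as many as the real 2049 (highest other 74), for 6 h against 3 h 1 of 100 (262, highest other 5), and for HGF 6 h 3 of 100 (1110). There the highest other was 2650, in a split that parts the pairs of 2 cultures only and follows the response of Detroit562. Most of these splits break the pairing by culture, so all 32 that part every pair were fitted as well. Of these 1 of 32 gave as many at 3 h (highest other 1), 1 of 32 at 6 h (highest other 4) and 1 of 32 for 6 h against 3 h (highest other 4). The 2 cultures of a line share the line's response, so a swap in 1 of them sets like responses against each other. That lowers the count beforehand, so these splits do not exclude chance. With the genotypes summed and 3 lines as replicates edgeR called 0 genes at 3 h (3285 at an unadjusted p under 0.05), 0 at 6 h (2763) and 1 for 6 h against 3 h. DESeq2 called 1029, 513 and 189. With the times swapped in whole lines there are 4 splits, too few for a share under 0.05. For the interactions 0 genes were called, so every split gives as many, and the 10 of 10 at 3 h and at 6 h were fixed beforehand. The highest others were 18 and 49, and these splits too are too few for a share under 0.05.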
